A study of Drosophila melanogaster with 12 samples.

How the data were processed

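Expression was measured on 12 Affymetrix arrays, each hybridized with RNA from the eye-antennal imaginal discs of wandering third-instar Drosophila melanogaster larvae. Per the labels, 30 pairs of discs were dissected for each array, total RNA was extracted with Trizol, and 100 ng of it was turned into biotin-labelled RNA by in vitro transcription from cDNA made in 2 rounds. The arrays fall into 4 genotypes with 3 biological replicates each: the driver ey-Gal4 alone, the transgene UAS-wge alone, both together (ey>wge), and both together in larvae carrying the alleles Su(var)3-9[1] and Su(var)3-9[2]. No dissection, labelling or scanning date is recorded, so no batch could be modelled.

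The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array, for 18952 probe sets. MAS5 is named in the submitters' processing notes without a version or settings. After 2% of the probe sets at each end were left out, the mean of every deposited array lay at 500.01 or 500.02, so the arrays had been scaled to a common level before deposition. Detection calls were not used here. The number of arrays per genotype limits the precision, and no count or depth exists for this kind of data.

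Signals were analysed as log2(signal + 16) with no further normalization. A probe set was tested if it lay above its array's own 40th percentile on at least 3 of the 12 arrays, and the 183 Affymetrix control probe sets were left out, which left 13817. Gene symbols came from the platform annotation and the same supplied table of Drosophila genes used for gene span. Of the probe sets tested, 10812 carried 1 symbol, 324 carried several and 2681 carried none, and the single symbols covered 9739 genes. Probe sets with several symbols or none were counted but not named, and for this reason Su(var)3-9, eIF2gamma, w, Ubx, wg, N, hth and sd have no named probe set here.

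Linear models with 1 mean per genotype were fitted to all 12 arrays at once with limma 3.58.1 in R 4.3.3, with eBayes(trend = TRUE). Tests were two-sided, and a probe set counts as changed at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested. The contrasts were ey>wge against the average of both controls, ey>wge against each control, the allele pair against ey>wge, the allele pair against the average of both controls, and UAS-wge against ey-Gal4. Changes are given on the log2 scale with the standard error (SE) of the model, and signals as the mean with the standard deviation (SD) of 3 arrays.

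Before the data were examined, 35 gene lists were fixed, covering disc identities, signalling pathways, chromatin factors, stress responses and markers of other larval tissues. They hold 530 genes, of which 396 have a named probe set and 377 were tested, and 34 lists have 3 or more tested genes. The list of male dosage RNAs has none. The probe set with the highest mean over all arrays stands for a gene with several. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists, and again with the correlation estimated from the data. Counts within a list are given over all probe sets and adjusted over the list alone. The genes named in the text follow a rule fixed at the same time: wge, ey, Su(var)3-9 and w first, then the 12 higher and 12 lower single-gene probe sets with the largest change whose arrays do not overlap between the sides (5 and 5 for the secondary contrasts), then up to 4 members of each list with the smallest adjusted p. Where further members of a list are named, they were chosen after their values were seen.

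The share of the winged eye response kept with the allele pair is the slope through 0 of the change with the allele pair on the change without it. To share no array, the change without it was taken against ey-Gal4 and the change with it against UAS-wge. The trend of an array with gene span (the length from the start to the end of a gene) was measured over the 10752 probe sets with 1 symbol and a span, 99.4% of the single-gene probe sets tested, and removed with a loess curve in an alternative. The span came from the supplied gene table (assembly Release 6 plus ISO1 MT). The build behind the array's probe sets is not named, so no coordinates are given.

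Alternatives tried were quantile normalization, centring on array medians, pseudocounts of 1 and 64, no filter and a 60th percentile filter, a variance prior without a trend, array weights, the replicate number as a block, leaving out each array, fitting only the groups of a contrast, and stricter thresholds. For lists, the mean of all probe sets of a gene and the test fry were added. Fits with only replicate 1 of the allele pair and with the span trend removed were chosen after the arrays had been seen. On data simulated with 13817 probe sets of which 200 changed, the fit recovered 62% of changes of log2 1 and 94% of changes of log2 2 for ey>wge against both controls, with 1.89% false among its calls. For the allele pair against ey>wge it recovered 38% and 89% with 5.93% false, and for the 2 controls against each other 40% and 86% with 0.787% false. The simulation gave all genotypes the same spread and no span trend, so its rates do not carry over to the allele-pair arrays. A simulated share kept of 0.5, with no difference between the controls, was estimated as 0.476. In a separate simulation the photoreceptor and retinal differentiation list was shifted by log2 1, and camera called it and 1 other list of 34. Some other lists share genes with the shifted one, so that further call need not be false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.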

Results

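The series profiled eye-antennal discs in which winged eye (wge), a gene for a chromatin-associated BAH-domain protein, was overexpressed with the eyeless driver, a condition that per the series title brings about transdetermination of the disc. Each of 4 genotypes was measured on 3 arrays: ey-Gal4, UAS-wge, ey>wge, and ey>wge with the allele pair Su(var)3-9[1]/[2], which affects the histone H3 lysine methyltransferase of heterochromatin. Median signals lay between 38.7 and 43.7 on the 9 arrays of the first 3 genotypes. In the allele-pair group they were 44.4, 33 and 34 in replicates 1, 2 and 3. The first principal component, with 25.6% of the variance, placed allele-pair replicates 2 and 3 at 51.6 and 66.8, replicate 1 at 17.2 and the other 9 arrays between -29 and 2.4. The median SD within a group was 0.36 on the log2 scale in the allele-pair group and 0.23 to 0.25 in the others. In the same 2 replicates signal fell with gene span relative to ey>wge, with Spearman correlations of -0.302 and -0.398 across genes, which are not independent replicates. The other 10 arrays lay between -0.029 and 0.158. The p-values below rest on 1 spread per probe set, pooled over the 3 biological replicates of all 4 genotypes. For the allele-pair group this pooled spread is typically smaller than its own.

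The probe set for wge read 846 ± 93 (SD, n = 3) in ey-Gal4, 853 ± 69 in UAS-wge, 1067 ± 126 in ey>wge and 663 ± 216 with the allele pair. The rise of 0.32 ± 0.17 (SE) in ey>wge over both controls did not pass the test (adjusted p = 0.498), and whether the transgene contains the probed sequence is not recorded. The fall of wge with the allele pair against ey>wge was -0.72 ± 0.20 (adjusted p = 0.0358).

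Discs expressing winged eye were compared with both parental controls to find the genes that respond to it. Antp, the Hox gene of the second thoracic segment, read 39.2 ± 12.9 in ey-Gal4 and 19.9 ± 15.6 in UAS-wge against 708 ± 244 in ey>wge (SD, n = 3 each), a change of 4.04 ± 0.34 (SE). The UAS-wge signal is at background, so the size depends on the pseudocount (4.85 with 1 and 3.02 with 64). The dorsal wing selector ap went from 120 ± 39 and 72.9 ± 16.2 to 1346 ± 29, a change of 3.65 ± 0.22, and the wing selector vg rose by 2.93 ± 0.28. Of 25 photoreceptor and retinal differentiation genes 20 fell at the same time: gl, a zinc-finger factor of photoreceptor development, fell by 2.17 ± 0.16 from 3707 ± 425 and 3607 ± 452 to 801 ± 71, and sev, the receptor that specifies photoreceptor R7, fell by 2.78 ± 0.45. In the limma fit 410 of 13817 probe sets changed, 124 higher and 286 lower, and 60 of the higher and 214 of the lower ones changed at least 2-fold. With only the 9 arrays of these groups in the fit the count was 722. It was 250 without ey>wge replicate 3 and 625 without replicate 1 of the allele pair, which enters only through the shared spread. The 124 higher became 77, 73 and 60 without ey>wge replicates 1, 2 and 3, and 224 without replicate 1 of the allele pair.

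Among the 18 tested genes of the wing list, ap, vg, nub and Dr rose and 14 did not pass, and 5 rose and 1 fell adjusted over the list alone. nub, a POU factor of the wing pouch and hinge, changed by 2.32 ± 0.20, from 198 ± 39 and 126 ± 43 to 833 ± 32, and the homeobox gene Dr changed by 2.35 ± 0.26. All 4 also passed against each control. The list was called higher (adjusted p = 0.00152; adjusted p = 0.169 with an estimated correlation). Of the 4 tested Hox genes, Antp rose and Scr, Dfd and pb did not pass, while 3 rose adjusted over the list alone. The Hox list was called (adjusted p = 0.000268; adjusted p = 0.0426 with an estimated correlation). Scr measured 218 ± 103 in ey>wge against 102 ± 68 in ey-Gal4, a change of 1.48 ± 0.41 against both controls (adjusted p = 0.0623).

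**Figure D1:**
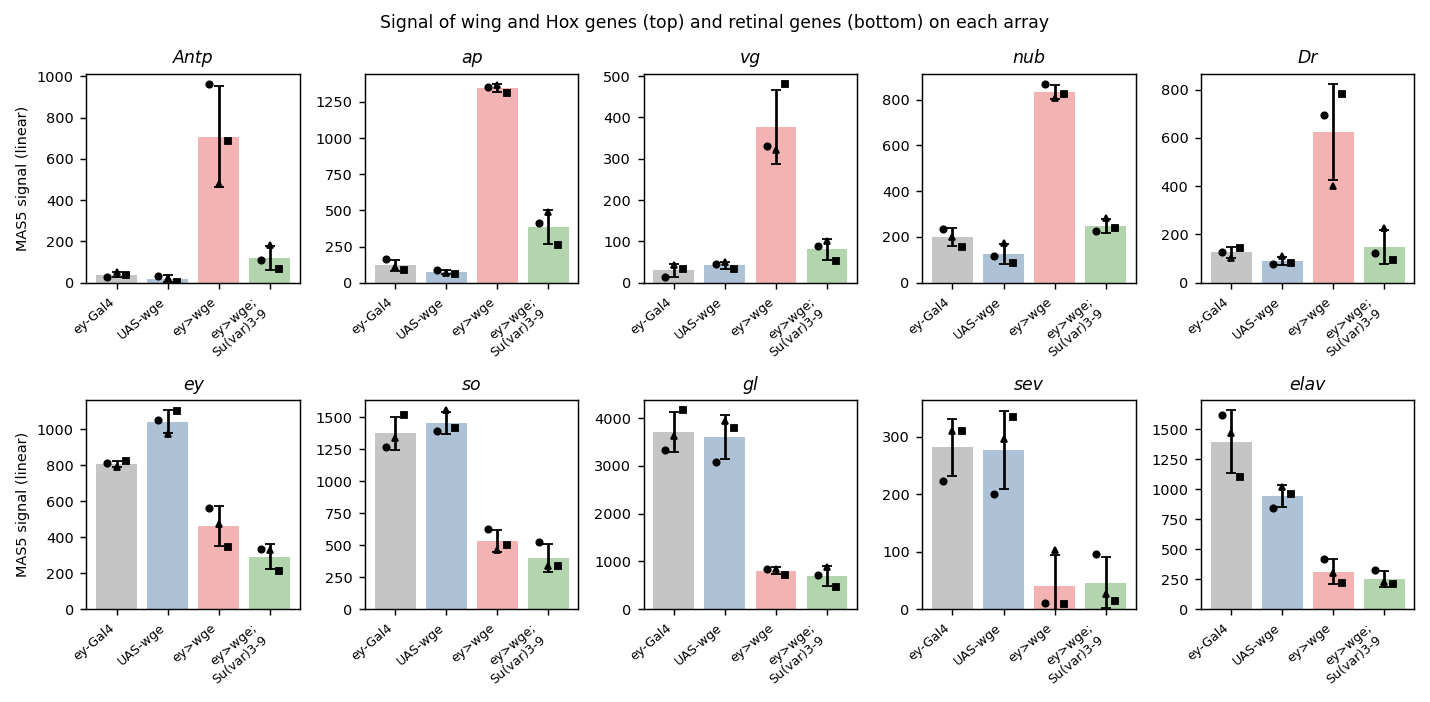
MAS5 signal of 5 wing and Hox genes and 5 retinal genes in the 4 genotypes. Bars are means of 3 arrays, error bars are 1 SD (shown from 0 upward), and circles, triangles and squares are replicates 1, 2 and 3. For ap the ey>wge mean is 1346 against 120 in ey-Gal4, and for gl it is 801 against 3707.

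In the notum, hinge and body wall list, 4 of 12 genes rose, namely caup by 0.82 ± 0.14, sr by 1.13 ± 0.24, ara and tsh, and none fell. The count adjusted over the list alone was 7 higher. caup and ara are Iroquois homeobox genes that pattern the notum. The list was called higher (adjusted p = 1e-06; adjusted p = 0.0426 with an estimated correlation). In the leg list 4 of 16 rose (ap, tsh, drm and odd) and dac fell, with 7 higher and 1 lower adjusted over the list alone (adjusted p = 9.09e-05; adjusted p = 0.0508 with an estimated correlation). Of these, drm and odd also differed between the parental controls, by -0.91 ± 0.13 and -0.93 ± 0.16 in UAS-wge against ey-Gal4. In ey>wge drm measured 3935 ± 310 against 3110 ± 273 in ey-Gal4 and 1666 ± 325 in UAS-wge.

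Of 12 retinal determination genes, 8 fell and tsh rose. The Pax6 genes toy and ey changed by -1.47 and -0.999 ± 0.169, and so, eya and dac, which act with them in specifying the eye field, by -1.40, -1.61 ± 0.19 and -1.48 ± 0.17. ey measured 808 ± 17 in ey-Gal4, 1043 ± 63 in UAS-wge and 460 ± 111 in ey>wge. Counts adjusted over the list alone were 2 higher and 8 lower. The list was called lower (adjusted p = 1.26e-11; adjusted p = 0.0508 with an estimated correlation). Of 25 photoreceptor and retinal differentiation genes, 20 fell and none rose. The examples are gl and sev, the proneural gene ato (-1.34), the neuronal RNA-binding protein gene elav (-1.86) and the sev pathway gene phyl (-1.64), and 21 fell adjusted over the list alone (adjusted p = 1.08e-32; adjusted p = 0.0148 with an estimated correlation). The axon guidance gene gogo (-2.37) and the ankyrin gene Ank2 (-2.25) were among the 12 single-gene probe sets with the largest falls, with twit, superdeath, CG12071, RhoGAP100F and CG9119.

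Neighbouring lists held some of the same genes. In the antenna list dan, danr and B-H2 fell of 14 genes, with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.00967; adjusted p = 0.31 with an estimated correlation, and 0.114 with the span trend removed). Of these, dan and danr also belong to the retinal list and B-H2 to the photoreceptor list. In the brain and neuroblast marker list elav, brp and nSyb fell of 11, with 3 lower adjusted over the list alone (adjusted p = 0.00152; adjusted p = 0.0508 with an estimated correlation). All 3 are also in the photoreceptor list. Of 49 list genes with several probe sets, 10 were called in only part of them and none in opposite directions. Among these, Antp and toy passed on 2 of 3 each, brp on 1 of 4 and futsch on 1 of 3. For nub, vvl and Cadps it was 1 of 2 each. Of 36 chromosome 4 genes, ey, toy, Ekar (-1.92), onecut (-1.90) and Cadps (-1.11 ± 0.24) fell and none rose, with 7 lower adjusted over the list alone (adjusted p = 0.00259; adjusted p = 0.337 with an estimated correlation). Camera did not call the chromosome 4 list against UAS-wge alone (adjusted p = 0.139).

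Among signalling genes, Ilp8, a relaxin-like peptide released by discs with disturbed growth, rose. It read 22.3 ± 19.8 in ey-Gal4, 7.40 ± 4.78 in UAS-wge and 709 ± 224 in ey>wge, a change of 4.62 ± 0.30. Its control signals lie at background, so the size depends on the pseudocount (5.86 with 1 and 3.27 with 64). In the JNK and regeneration list, Ilp8, rgn and grnd rose of 23 genes, and the matrix metalloproteinase gene Mmp2 (-2.09) and scaf (-1.43 ± 0.23) fell, with 6 higher and 3 lower adjusted over the list alone (adjusted p = 0.0271; adjusted p = 0.561 with an estimated correlation; 0.184 by fry). Camera did not call this list against ey-Gal4 alone (adjusted p = 0.379) or UAS-wge alone (adjusted p = 0.134). rgn differed between the controls, with 5903 ± 974 in ey-Gal4, 84.3 ± 15.5 in UAS-wge and 2872 ± 81 in ey>wge, and it fell against ey-Gal4 alone by 1.02. In the JAK/STAT list the ligand gene upd1 rose by 1.72 ± 0.27 of 5 genes, with 2 higher adjusted over the list alone (adjusted p = 0.00821; adjusted p = 0.0685 with an estimated correlation). The JAK/STAT list was not called by camera against UAS-wge alone (adjusted p = 0.0903).

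Of 14 tested genes of the Notch list, falls included E(spl)mdelta-HLH (-1.44 ± 0.11), E(spl)m4-BFM (-1.43 ± 0.18), E(spl)m7-HLH (-0.71 ± 0.13) and E(spl)m2-BFM (-0.65 ± 0.14). With 1 higher and 9 lower adjusted over the list alone, the list was called lower (adjusted p = 2.94e-07; adjusted p = 0.0945 with an estimated correlation). In the EGFR list the transcriptional repressor gene aop (-0.81) and the secreted inhibitor gene aos (-1.06) fell of 9, the same count adjusted over the list alone (adjusted p = 0.00229; adjusted p = 0.276 with an estimated correlation; 0.113 by fry). Against UAS-wge alone camera did not call the EGFR list (adjusted p = 0.0693).

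Hemocyte markers were lower than the average of the controls in 7 of 12 genes, among them Hml (-1.49 ± 0.18) and Pxn (-1.19 ± 0.20), with 8 lower adjusted over the list alone (adjusted p = 5.56e-11; adjusted p = 0.0508 with an estimated correlation). The controls differed in the same genes. Pxn measured 273 ± 68 in ey-Gal4, 1427 ± 333 in UAS-wge and 261 ± 23 in ey>wge. Against UAS-wge 8 of the 12 fell, and 10 adjusted over the list alone. Against ey-Gal4 limma called 0 of the 12 (1 higher and 1 lower adjusted over the list alone), where 1829 of all 13817 probe sets had an unadjusted p under 0.05, and the list was not called (adjusted p = 0.894). The prophenoloxidase gene PPO1 of crystal cells, which was among the largest falls (-2.13), also fell against UAS-wge by 2.96.

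The other 20 lists were not called by camera. In them magu of the Dpp list (0.83 ± 0.11), Act87E of the muscle list (0.70) and vvl of the trachea list (1.32 ± 0.32) rose, loco of the glia list fell by 0.92 ± 0.12, and each count was the same adjusted over the list alone. magu also differed between the controls (-0.53 ± 0.13). No member passed on its probe set of highest signal in the Wingless, Hedgehog, Hippo, Polycomb, Trithorax, heterochromatin factor, pericentric gene, cell cycle, apoptosis, heat shock, antimicrobial, ecdysone, fat body, salivary gland, gut and reference lists, while limma gave 1635 of 13817 probe sets an unadjusted p under 0.05. The Hedgehog list gene rdx was lower on the other of its 2 probe sets. Adjusted over the list alone, 1 Polycomb gene (Asx, -0.49) and 1 cell cycle gene (CycD, -0.40) fell. Their camera adjusted p-values ranged from 0.0893 for glia and 0.108 for Polycomb and muscle to 0.939 for Hedgehog, heat shock and gut. The mean of the Hedgehog list was 0.03 and that of the heat shock list 0.04, and camera gave both as lower. The medians of the Dpp (-0.02), pericentric (-0.00) and apoptosis (-0.05) lists differed in sign from their means of 0.09, 0.06 and 0.14, as did the cell cycle list with a median of 0.00 and a mean of -0.03.

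Against each control separately, the named wing genes and Ilp8 rose and the named retinal genes fell in both tests. Antp rose by 3.68 over ey-Gal4 and also passed over UAS-wge, and sev fell by 2.79 and 2.76. In all, 502 probe sets changed against ey-Gal4 (186 higher, 316 lower) and 511 against UAS-wge (240 higher, 271 lower). Of these, 195 changed in the same direction against both, 31 higher and 164 lower, and 26 changed in opposite directions. Of the 410 probe sets changed against the average of the controls, 215 did not pass against each control and 86 differed between the controls. The count of 195 became 128 without ey>wge replicate 3. The 31 higher became 20 and 18 without ey>wge replicates 1 and 3, and 62 and 48 without allele-pair replicates 1 and 3.

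The parental genotypes were compared to measure line differences. In UAS-wge discs 8 of 12 hemocyte genes were higher than in ey-Gal4: Nplp2 by 3.39 ± 0.28 (6374 ± 2106 against 614 ± 255), NimC1, a phagocytosis receptor, by 3.24 ± 0.28, and Pxn by 2.32 ± 0.23. The count adjusted over the list alone was 9 (adjusted p = 2.92e-17; adjusted p = 0.0809 with an estimated correlation). Muscle markers were lower in 2 of 9, up (-1.46 ± 0.35) and Tm2 (-1.20 ± 0.31), both of the contractile apparatus, and in 7 adjusted over the list alone (adjusted p = 0.000862; adjusted p = 0.832 with an estimated correlation; 0.165 by fry). The cuticle protein gene TwdlG (4.81 ± 0.31) and mthl8 (4.43 ± 0.26) were among the named rises, and the axonemal protein gene Tektin-C (-6.43 ± 0.26), rgn (-5.88 ± 0.17), CG14957 (-5.46) and Rab40 (-3.74 ± 0.23) among the named falls. Tektin-C read 9.73 ± 11.36 in UAS-wge, at background, so the size depends on the pseudocount (-8.15 with 1 and -4.87 with 64). TwdlG and mthl8 in ey-Gal4 and CG14957 in UAS-wge were also at background. In total 690 probe sets changed, 319 higher and 371 lower. The count was 457 without UAS-wge replicate 2, 461 without ey-Gal4 replicate 3 and 490 without UAS-wge replicate 3. The 319 higher became 204 without UAS-wge replicate 2 and 208 without ey-Gal4 replicate 3.

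The other 32 lists were not called between the controls. Members passed in 7 of them: chp (-1.02 ± 0.22) and futsch (0.89 ± 0.24) of the photoreceptor list, btd (1.33 ± 0.22) and bowl (0.56) beside drm and odd of the leg list, wnd (1.79 ± 0.20) beside rgn of the JNK list, magu, Sce (0.68) of the Polycomb list, osa (1.30) of the Trithorax list, and Actbeta (1.92), yellow-h (-1.41) and bt (-1.30) of the chromosome 4 list. Adjusted over the list alone the counts were 2 higher and 3 lower for leg, 1 higher and 2 lower each for JNK and Dpp, and 1 higher for gut, and as over all probe sets in the rest. The wing, retinal, antenna and Hox lists had no member past the test, also adjusted over the list alone. limma gave 1930 of 13817 probe sets an unadjusted p under 0.05 in this contrast. Median and mean differed in sign for the notum, retinal, JNK, JAK/STAT, Wingless, Polycomb, pericentric, fat body, glia, trachea, gut and reference lists, and camera gave Hippo as lower at a mean of 0.07.

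The allele pair was set against ey>wge to measure how discs that carry it differ under winged eye expression. No group carries the alleles without ey>wge, so an effect of the alleles or their stock alone cannot be told from one that needs winged eye. Of 18 wing genes 8 fell with the allele pair and 10 did not pass. The Hox gene Antp fell by 2.44 ± 0.39, from 708 ± 244 to 120 ± 57 (SD, n = 3), and vg fell by 2.04 ± 0.33 to 80.5 ± 24.9. The changes of Dr, ap and nub were -1.99 ± 0.30, -1.80 ± 0.25 and -1.69 ± 0.23, to 149 ± 70, 386 ± 117 and 249 ± 30. These 5 genes also fell with only allele-pair replicate 1, which has no span trend (from -1.67 ± 0.30 for ap to -2.45 ± 0.51 for Antp), and with the span trend removed (from -1.37 ± 0.23 to -2.09 ± 0.38). Replicate 1 differs in another way: the median of 6 fat body genes lay 1.59 above ey>wge in it (1 passed), against 0.53 over all 3 replicates. The Notch target E(spl)m2-BFM rose from 1760 ± 327 to 4676 ± 1114. The retinal genes eya (-0.06 ± 0.22) and dac (-0.07 ± 0.20) did not pass. In all, 939 probe sets changed, 308 higher and 631 lower, and 70 and 308 of them at least 2-fold. The count was 173 (65 higher, 108 lower) with only replicate 1 of the allele pair, 397 without its replicate 3, 314 without its replicate 2 and 2927 without its replicate 1. With the span trend removed it was 619, of which 298 were higher and 321 lower, against 829 uncorrected on the same probe sets, and 498 were called both ways. Of the 49 list genes with several probe sets 17 were called in only part of them and none in opposite directions. Among these, Antp passed on 2 of 3, and futsch and toy on 1 of 3 each. The genes nub, H, mirr, chinmo, ADD1 and Cadps passed on 1 of 2 each. Without 1 of the ey>wge replicates the count of changed probe sets was 343, 391 and 405.

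**Figure D2:**
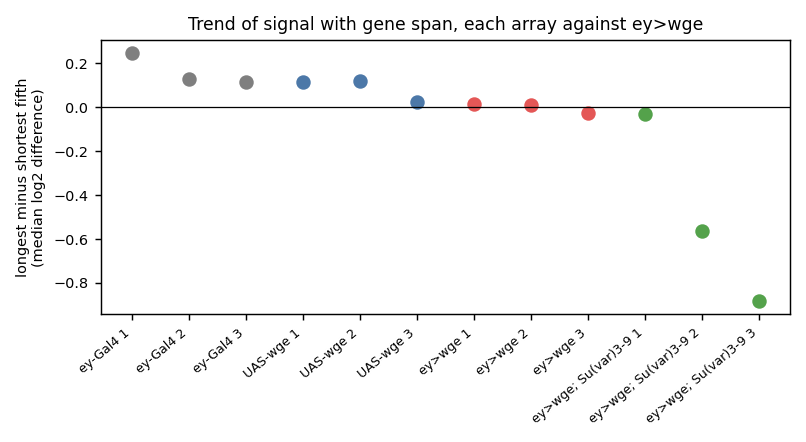
Difference on the log2 scale between the longest and the shortest of 5 equal groups of genes by span, as the median over probe sets of each array's value minus the ey>wge mean, for each of the 12 arrays. Replicates 2 and 3 of the allele pair lie at -0.565 and -0.884, and replicate 1 at -0.03.

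In the wing list 8 of 18 genes fell with the allele pair and none rose. Beside ap, vg, nub and Dr these include the protocadherin gene ds (-1.48 ± 0.35), fj (-0.76 ± 0.15) and salm (-0.68 ± 0.18), which did not change between ey>wge and the controls by the test. Adjusted over the list alone, 1 rose and 10 fell (adjusted p = 0.000762; adjusted p = 0.661 with an estimated correlation). With only allele-pair replicate 1, 4 fell, and with the span trend removed 6 fell. The Hox gene Antp was the only one of 4 to pass, also adjusted over the list alone, and the list was not called (adjusted p = 0.42).

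In the Notch list 8 of 14 genes rose and H, a repressor of Notch targets, fell. E(spl)m2-BFM rose by 1.39 ± 0.17, E(spl)malpha-BFM by 1.36 ± 0.21, E(spl)m7-HLH by 1.01 ± 0.15 and E(spl)m3-HLH by 0.96. The counts were 8 higher and 2 lower adjusted over the list alone (adjusted p = 0.000811; adjusted p = 0.661 with an estimated correlation). With only allele-pair replicate 1, 5 rose and none fell, and with the span trend removed 6 rose and none fell. E(spl)m2-BFM and E(spl)malpha-BFM lay above the controls (0.75 ± 0.14 and 0.72 ± 0.18 against both), and E(spl)mdelta-HLH (-0.93 ± 0.11) and E(spl)m4-BFM (-0.70 ± 0.18) stayed below them.

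Muscle and myoblast markers fell in 6 of 9 genes, among them Mlc2 (-1.65 ± 0.42), up (-1.64 ± 0.35) and Tm2 (-1.43 ± 0.31), with 7 lower adjusted over the list alone (adjusted p = 0.000762; adjusted p = 0.661 with an estimated correlation). With only allele-pair replicate 1, limma called 0 of the 9, with 4 at an unadjusted p under 0.05, and with the span trend removed 5 fell. The list was not called with replicate 1 alone (adjusted p = 0.0661). In the JNK list scaf (-2.33 ± 0.26), cher, Mmp2 and rgn (-0.87 ± 0.17) fell of 23, with 1 higher and 9 lower adjusted over the list alone (adjusted p = 0.00918; adjusted p = 0.661 with an estimated correlation; 0.0873 by fry). With only replicate 1 of the allele pair 1 gene rose and 1 fell and the list was not called (adjusted p = 0.852), and with the span trend removed 3 rose and 3 fell. The heat shock list was called higher (adjusted p = 0.0118; adjusted p = 0.661 with an estimated correlation), but not with quantile normalization (0.0774) or by fry (0.192 by direction, 0.352 mixed). No heat shock gene passed over all probe sets, where limma gave 3152 an unadjusted p under 0.05, and 3 of 5 rose adjusted over the list alone. Hsp68 measured 12316 ± 10377 with the allele pair and 1944 ± 606 in ey>wge. With only replicate 1 of the allele pair limma called 0 of the 5, also at an unadjusted p under 0.05, and the list was not called (adjusted p = 0.642).

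**Figure D3:**
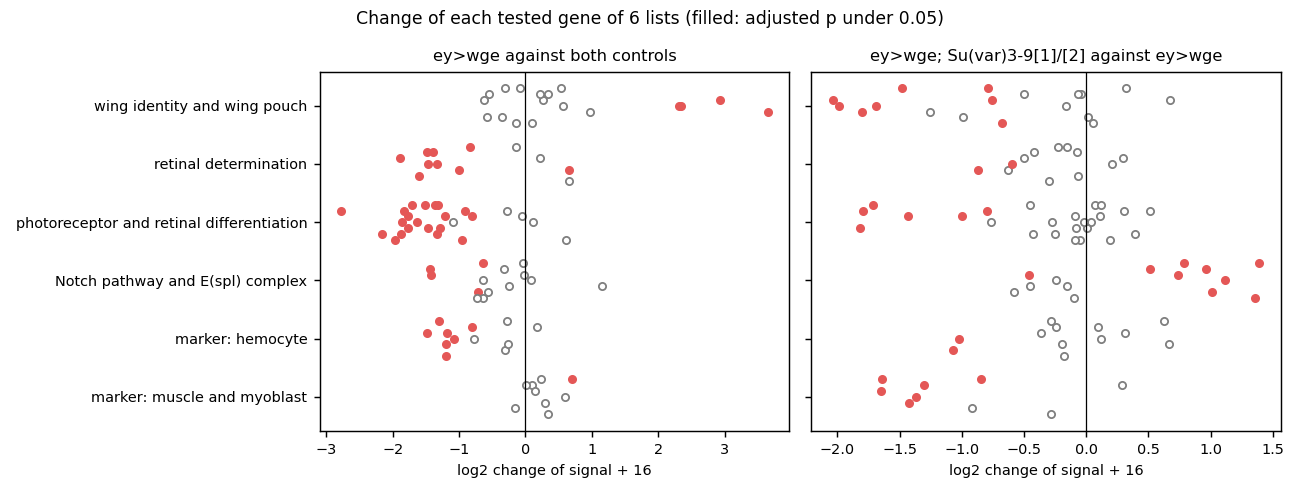
Change of every tested gene of 6 lists on the log2 scale of signal + 16, in ey>wge against both controls (left) and with the allele pair against ey>wge (right). Filled points passed at an adjusted p under 0.05, open points did not, and vertical offsets only separate the points. On the left 20 of 25 photoreceptor genes are lower, and on the right 8 of 18 wing genes are lower and 8 of 14 Notch genes higher.

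Named rises with the allele pair were in Zip102B, a zinc transporter gene on chromosome 4 (41.1 ± 27.2 in ey>wge, 912 ± 169 with the allele pair, change 4.13 ± 0.34), the translation factor gene eIF4E3 (2.68 ± 0.37), CG13029 (2.40 ± 0.30), Cadps (2.23 ± 0.28), ImpL1 (2.22 ± 0.41) and Obp99a (2.11 ± 0.17). Named falls were in Tektin-C (-5.75 ± 0.26, to a signal at background), CG4408 (-3.94 ± 0.51), spok (-3.52 ± 0.75), GstE14 (-3.30), nvd (-2.92) and nolo (-2.84 ± 0.36). GstE14 and nvd were at background in allele-pair replicates 2 and 3, and nolo in replicate 3, so these sizes depend on the pseudocount (-4.93, -3.62 and -3.95 with 1, and -2.13, -2.05 and -1.86 with 64). Cby, cac, CG12481, CG33099, Rnf11 and cGlr2 complete the 12 named rises, and CG42788, CG31676, cu and Antp the falls. Further ecdysone synthesis genes of the prothoracic gland, phtm (-2.68 ± 0.57) and sad (-2.65), were among the 12 largest falls as well. Tektin-C, CG4408, CG13029 and Obp99a also differed between the parental controls, by -6.43, -2.97, -1.92 and 2.92, as did GstE14 (3.21 ± 0.76), CG12481, Rnf11 and CG33099. Signal of spok varied within groups, from 1915 to 11685 in UAS-wge and from 112 to 2061 with the allele pair, where replicate 1 was the highest.

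The remaining 29 lists were not called for the allele pair against ey>wge. In the photoreceptor list 6 of 25 fell, among them chp (-1.80 ± 0.22), futsch (-1.82 ± 0.24) and Appl (-1.71 ± 0.31), with 6 adjusted over the list alone (adjusted p = 0.122), and in the retinal list toy and tsh fell, with 3 lower adjusted over the list alone (adjusted p = 0.182). With only allele-pair replicate 1 limma called 2 and 0 of them, the latter with 3 at an unadjusted p under 0.05. Among chromosome 4 genes Zip102B, Cadps, dati and fuss rose and 5 of 36 fell, with 4 higher and 10 lower adjusted over the list alone (adjusted p = 0.231). With only replicate 1 of the allele pair 2 rose and none fell. Of 18 heterochromatin factors, HP4 (0.78 ± 0.16) and HP1c (0.68 ± 0.14) rose and Su(var)2-HP2 (-1.09 ± 0.27), ADD1, JIL-1 and Hmr fell. Adjusted over the list alone, 5 rose and 6 fell (adjusted p = 0.962), and with only replicate 1 limma called 0, with 5 at an unadjusted p under 0.05. Pericentric genes had 2 higher (Haspin and Dbp80) and 1 lower (nvd) of 16, and 3 and 2 adjusted over the list alone (adjusted p = 0.44).

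Elsewhere single members passed. Notum genes tsh and mirr fell (adjusted p of the list 0.266). The antenna list (0.44) and the leg list (0.419) each had 2 higher and 2 lower genes. In the signalling lists chinmo of the JAK/STAT list (0.201), Axn of the Wingless list (0.988), shn and Dad of the Dpp list (0.248), Egfr (-1.14 ± 0.21) and kek1 of the EGFR list (0.23), and fj and ds of the Hippo list (0.151) fell. Pcl and Jarid2 of the Polycomb list (0.266) and Kdm5 and kis of the Trithorax list (0.0706) fell, and ImpL1 and MsrA of the ecdysone list (0.962) rose. Among tissue markers the blood-brain barrier gene moody (-1.62 ± 0.26) and loco of the glia list (0.182), vvl of the trachea list (0.374), and Ppn and srp of the hemocyte list (0.825) fell, and the ribosomal protein gene RpL32 of the reference list (0.23) rose by 0.41 ± 0.10. Adjusted over the list alone, falls numbered 2 for JAK/STAT, trachea and notum, 3 for Dpp, glia and antenna, 4 for Trithorax and 1 each for ecdysone and fat body, 3 leg genes rose, and the other counts of this paragraph stayed as they were. No member passed in the Hedgehog (0.44), cell cycle (0.988), apoptosis (0.898), antimicrobial (0.888), fat body (0.44), salivary gland (0.962), brain (0.973) and gut (0.898) lists, where limma gave 3152 of 13817 probe sets an unadjusted p under 0.05. Camera's direction differed in sign from the mean for the leg, Wingless, pericentric, apoptosis, antimicrobial and brain lists, whose means were -0.07, 0.03, -0.21, -0.01, -0.00 and -0.10. In the following lists, whose named members all fell, the median was higher with only allele-pair replicate 1, which has no span trend. It went from -0.247 to -0.006 for Trithorax, -0.329 to -0.001 for Hippo, -0.392 to 0.003 for glia and -0.229 to 0.057 for notum. Polycomb went from -0.155 to -0.055 and JAK/STAT from -0.402 to -0.166. These lower medians thus rest mainly on replicates 2 and 3. Both carry the trend, and their array medians were also lower (33 and 34 against 44.4 in replicate 1), which was not separated from it. The medians of the Dpp (-0.213), EGFR (-0.202), trachea (-0.558) and hemocyte (-0.187) lists, also negative over all replicates, are not compared here.

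The allele pair was also compared with both controls to measure how much of the winged eye response remains. Photoreceptor genes stayed low: 22 of 25 fell, among them futsch (-3.59 ± 0.21), Appl (-3.43 ± 0.27) and gl (-2.42 ± 0.16), with 1 higher and 22 lower adjusted over the list alone (adjusted p = 1.16e-16; adjusted p = 0.12 with an estimated correlation). Of 12 retinal determination genes 8 fell, also adjusted over the list alone, with ey at -1.63 ± 0.17 (adjusted p = 9.58e-08; adjusted p = 0.306 with an estimated correlation). The wing list had 3 higher and 5 lower genes of 18 and was not called (adjusted p = 0.86). Antp (1.60 ± 0.34), ap (1.85 ± 0.22), vg (0.89) and nub (0.63) remained above the controls, and Ilp8 by 3.92 ± 0.30. With Antp at background in UAS-wge and Ilp8 in both controls, these sizes depend on the pseudocount (2.24 and 5.14 with 1, and 0.95 and 2.62 with 64). In all, 2920 probe sets changed, 1169 higher and 1751 lower. The count was 657 (230 higher, 427 lower) with only allele-pair replicate 1, with which 17 photoreceptor and 7 retinal genes fell. It was 1757 without its replicate 2 and 1693 without its replicate 3. The excess of lower calls turned with the scaling, to 1408 higher and 1288 lower after centring on array medians and to 1239 and 889 with the span trend removed.

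Of the other lists against both controls, leg was called higher (7 of 16 rose and dac fell, adjusted p = 0.00273; 0.306 with an estimated correlation) and so was heat shock (Hsp26 and Hsp68 of 5, and 4 adjusted over the list alone, adjusted p = 0.0318; 0.519). Lower lists were hemocyte (6 of 12, 10 adjusted over the list alone, adjusted p = 2.16e-05; 0.318), EGFR (6 of 9, 7 adjusted over the list alone, adjusted p = 0.00184; 0.334), chromosome 4 (6 higher and 14 lower of 36, 6 and 16 adjusted over the list alone, adjusted p = 0.0318; 0.519), muscle (5 of 9, 6 adjusted over the list alone, adjusted p = 0.0392; 0.512) and glia (3 of 6, also adjusted over the list alone, adjusted p = 0.0392; 0.446). The second value of each pair is the adjusted p with an estimated correlation. With only replicate 1 of the allele pair the lower counts were 4 for hemocyte, 1 for EGFR, 7 for chromosome 4, 0 for muscle (limma, with 1 at an unadjusted p under 0.05) and 1 for glia, and 5 leg genes rose. No heat shock gene passed then, also at an unadjusted p under 0.05. With that replicate alone the chromosome 4 (adjusted p = 0.0632), glia (0.107), heat shock and muscle (0.473 each) lists were not called. With the span trend removed EGFR (adjusted p = 0.106) and chromosome 4 (0.395) were not called. With quantile normalization heat shock (adjusted p = 0.234) and muscle (0.0581) were not called, nor was muscle on the mean of all probe sets (0.0517), nor heat shock by fry (0.131 by direction, 0.269 mixed). The remaining 25 lists were not called. Their median and mean differed in sign for the JAK/STAT, Notch, pericentric, antimicrobial, ecdysone and gut lists.

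Between the comparisons, 31 of the 124 probe sets higher in ey>wge were lower with the allele pair against ey>wge, where independent lists of these sizes would share 5.66, and 13 of the 286 lower ones were higher (6.38 for independent lists). In the same direction went 5 of the higher ones (2.76 for independent lists) and 45 of the lower ones (13.1). Both contrasts use the ey>wge arrays, which alone gives a correlation of -0.578 across probe sets in simulated data without any effect, against -0.251 observed. Among probe sets called against each control, 14 of the 31 higher ones fell with the allele pair and none rose, and of the 164 lower ones 34 fell further and 7 rose. These sets were selected on the ey>wge arrays that the allele pair is compared with, which by itself moves values back towards the controls, and no expected count was computed. Over the 502 probe sets called in ey>wge against ey-Gal4, the share of the response kept was 0.529, with 0.43, 0.509 and 0.648 in replicates 1, 2 and 3 (SD 0.11, n = 3). With the controls exchanged it was 0.31, and with both controls in both changes, which share arrays, 0.973. In the first 2 settings a difference between the controls enters the 2 changes with opposite sign. As 690 probe sets differed between the controls, this pulls 0.529 and 0.31 down, and neither measures how much of the response was lost. For the 31 probe sets that rose against each control the share kept was 0.558, and for the 164 that fell 1.22. But these sets were selected on the UAS-wge arrays too, which can raise the share to an extent that was not tested. Over the 250 that fell in the fit with only replicate 1 of the allele pair it was 0.965.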

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

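The tests of the span trend, of a weaker response as a whole, of RNA degradation and of ring gland tissue were chosen after the results they bear on had been seen, and the counts of other splits of the samples were planned. Single outlying arrays were not tested for.

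The spike-in controls dap, lys and thr, which none of the comparisons use, read higher with the allele pair than in the 6 control arrays. The mean signal of the 3' probe set was 1709 against 675 for dap, 213 against 89.5 for lys and 218 against 108 for thr. In each case all 3 allele-pair arrays lay above all 6 controls. The ey>wge means lay between these, at 983 for dap, 117 for lys and 124 for thr. Of the other poly-A controls, phe (194 against 82.4) had allele-pair replicate 1 below the highest control, and trp read 8.40 against 11.4. The hybridization control bioB read 63.1 in allele-pair replicate 1 and between 316 and 579 on the other 11 arrays. The control bioC read 736 in that replicate and between 1079 and 2031 on the others.

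With the allele pair ap, vg, nub, Dr and Antp were lower than in ey>wge while the retinal genes stayed low. The span trend of allele-pair replicates 2 and 3 does not account for this, since the median change of the 5 genes was -1.884 in replicate 1, which lacks the trend, against -1.509 and -2.477 in the others, and all 5 still passed once the trend was removed (from -1.37 ± 0.23 to -2.09 ± 0.38). A winged eye response weakened alike in all its genes would also have reversed part of the fall of 28 retinal genes. The share reversed was 0.005 in replicate 1, and -0.111 and -0.372 in replicates 2 and 3, where the span trend could hide a reversal. This argues against such a weakening, but free of that trend it rests on replicate 1 alone. That array also had low bioB and bioC signals and a raised fat body median. The wing genes had moved back by 0.515 to 0.845, but they were picked for that fall. A lower wge signal and the genetic background brought in with the alleles were not separated from loss of Su(var)3-9 itself, and stay open.

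More probe sets were lower than higher with the allele pair against ey>wge, and whether the span trend of replicates 2 and 3 accounts for this stays open. Once it was removed, 51.9% of the calls were lower against 67.8% before on the same probe sets, but that correction also recentres each array. With only replicate 1, which lacks the trend, 62.4% of 173 calls were still lower, and after centring on array medians 478 of 753. Ratios of 3' to 5' control probe sets gave no sign of RNA degradation, as 0 of 6 in these arrays lay above those of all 10 others. The eIF-4a ratio was already between 10.56 and 17.07 on those others, so a moderate difference could be missed and degradation stays open. A true difference between long and short genes was not tested.

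Of 8 chosen genes of the prothoracic gland 6 fell with the allele pair (spok, nvd, phtm, sad, GstE14 and ouib), and 7 of all 13 candidates of that part. The span trend does not account for the change by itself, as the median over the 8 shrank by 3.2% (from -2.66 to -2.57) once it was removed, though it was -1.025 in replicate 1, the array without the trend. Whether differing amounts of ring gland tissue among the dissected discs account for it stays open: within groups, jhamt and Akh, made in other parts of that gland, deviated together with the 8 genes over 12 arrays (Pearson r = 0.912, exact permutation within groups p = 0.0054, Spearman rho = 0.839), but with the allele pair jhamt (-1.77), Akh (-0.74) and NPFR (-0.25) did not pass the test. Without the 2 arrays farthest from the median, r was 0.882 by distance in the 8 genes and 0.827 by distance in both sets. The 10 genes were picked after the values of 16 candidates had been looked at (r = 0.875 over all 16, exact permutation p = 0.00463), and shuffling over all arrays, tried first, gave a permutation p of 3e-05 that ignores the groups.

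When the 9 arrays of ey>wge and both controls were regrouped into 3 and 6, 3 of 84 splits gave as many probe sets, a share under 0.05. The real split gave 263 when the 6 shared a mean, unlike the fit behind the count of 410, and the highest other gave 372. The other 2 of these 3 separate the parental genotypes (UAS-wge with 372, ey-Gal4 with 283), a structure of the samples, and the next split gave 1. The share was also under 0.05 for the allele pair against both controls (1 of 84 splits, 2356 probe sets, highest other 351). For changes against each control it was 1 of 100 splits drawn from 840 (195, highest other 137). Whether the splits that set a parental genotype apart were among those drawn is not recorded, so this rank may depend on the draw. Such shares make a random assignment of arrays unlikely, but do not separate winged eye from a line or batch difference. For the allele pair against ey>wge (939, highest other 0) and for the 2 controls (690, highest other 1), the 10 splits are too few for a share under 0.05.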

How the results depend on the processing

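The fits with only allele-pair replicate 1, with the span trend removed, and the shares over probe sets called against each control were chosen after seeing the data, and the rest were planned. Apart from the values below, every total of changed probe sets stayed within 1.5 times its reported value under quantile normalization, median centring, the other pseudocounts and filters, the replicate block and the remaining settings. Replicate numbers do not pair the samples (correlations of deviations between -0.049 and 0.083 over 18 pairs), and with that block the counts were 423, 204, 1056, 3035 and 676 for ey>wge against both controls, against each, the allele pair against ey>wge and against both controls, and the 2 controls. With array weights the first 4 were 675, 317, 4409 and 6454. With only allele-pair replicate 1, whose lone array is assumed to vary like the other groups, all 5 were 724, 324, 173, 657 and 1045. With only the groups of the contrast the first 3 were 722, 327 and 252. At an adjusted p under 0.01 the 5 counts were 254, 120, 251, 1559 and 398, and with at least a 2-fold change the last 3 were 378, 874 and 393, both stricter by construction. The count of 410 became 195 when each control had to pass separately. The higher counts alone moved more: with a prior without a trend 124 became 74 for ey>wge against both controls and 1169 became 687 for the allele pair against both. For the allele pair against ey>wge that prior gave 281, and removing the span trend 619 (829 uncorrected on the same probe sets). Leaving out 1 array gave 250 (without ey>wge replicate 3) to 625 (without allele-pair replicate 1) for ey>wge against both controls, 128 to 279 against each (the same arrays), 314 to 2927 for the allele pair against ey>wge (without its replicates 2 and 1), 1693 to 4211 for the allele pair against both controls (without its replicates 3 and 1) and 457 to 966 between the controls (without UAS-wge replicate 2 and allele-pair replicate 1). The share kept, 0.529, ranged from 0.45 to 0.559 without 1 array. Differences between the controls pull 0.529 down, as they do the 0.31 with the controls exchanged and the 0.399 with only allele-pair replicate 1. The share was 0.973 with both controls in both changes. The selection of probe sets called against each control uses the arrays of both changes, which can raise the share. It also drops probe sets that passed against only 1 control, and neither influence was tested. Over the probe sets so selected the share was 1.056. For the lower ones of these it was 1.221, and 1.212 with the controls exchanged, but 0.965 and 0.973 with only allele-pair replicate 1, 1.062 and 1.082 without its replicate 3, and 1.114 and 1.028 with the span trend removed. Camera called 14 lists for ey>wge against both controls and 3 with an estimated correlation, where the adjusted p was 0.169 for wing and 0.0508 for retinal genes, and 0.661 for both wing and Notch genes with the allele pair against ey>wge. Under every setting chosen beforehand 49 of 61 named genes kept their call for ey>wge against both controls, 31 of 78 for the allele pair against ey>wge, 67 of 99 for the allele pair against both controls and 19 of 28 between the controls. In the allele pair against both controls 4 named genes reversed: shn (0.035), ds (0.22) and FASN1 (0.085) with only replicate 1, and RpL15 (-0.047) with quantile normalization. Where no construction is given, the cause was not tested. Background limits what dim genes can show: the 40th percentile of signal lay between 21.2 and 28.6.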

Other observations

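The test of parental copies and the choice of the chromosome 4 and signalling genes named here came after the values had been seen.

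Genes of chromosome 4, which carries much heterochromatin, went both ways with the allele pair. Zip102B rose from 41.1 ± 27.2 to 912 ± 169 (SD, n = 3), Cadps from 248 ± 69 to 1253 ± 517, fuss from 133 ± 39 to 268 ± 53 and dati from 25.2 ± 16.5 to 76.2 ± 15.1. In the same comparison bt, a giant muscle protein gene, fell by 1.86 ± 0.29, and toy by 0.59 ± 0.12. Allele-pair replicates 2 and 3, which carry the span trend, enter these falls, and bt was also lower in UAS-wge than in ey-Gal4. Cadps had fallen in ey>wge against both controls, by 1.11 ± 0.24, and lay 1.12 ± 0.24 above them with the allele pair, each on only 1 of its 2 probe sets.

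Ilp8 read 420 ± 82 with the allele pair and 709 ± 224 in ey>wge, and upd1 124 ± 36 and 246 ± 84. Neither difference passed the test (-0.70 ± 0.34 with adjusted p = 0.23, and -0.88 ± 0.32 with adjusted p = 0.0984), and the genes lay above the controls by 3.92 ± 0.30 (2.62 with a pseudocount of 64 and 5.14 with 1, as the controls are at background) and 0.84 ± 0.27.

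Whether genes that differ between the parental genotypes are present in ey>wge as 1 copy from each parent stays open. Over 393 such probe sets, the median position of ey>wge on the linear scale from ey-Gal4 (0) to UAS-wge (1) was 0.485, with quartiles of 0.285 and 0.67, and 60.3% lay between 0.25 and 0.75. Tektin-C read 2079 ± 85 in ey-Gal4, 9.73 ± 11.36 in UAS-wge and 1039 ± 42 in ey>wge. With the allele pair the median was 0.525 with quartiles of 0.0728 and 0.931, so a median near the middle does not show intermediate genes, and Tektin-C read 3.70 ± 2.44. A lower dose of ey-Gal4 or UAS-wge effects without such copies was not separated from this, and such genes enter the comparisons with either control.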
